A study of Mus musculus with 11 samples.

How the data were processed

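RNA from 3T3-L1 mouse preadipocyte cultures given CLA or LA for 4, 8 or 12 h was extracted with Trizol, turned into biotinylated cRNA and hybridised to Affymetrix arrays with 1 colour, per the labels' protocols. Groups, times and replicate numbers were taken from the labels of the 11 arrays. The number of arrays, 1 or 2 per group, limits the precision of every value.

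The deposited value table holds 1 probe set intensity per array on a linear scale, background-subtracted, since a share of the values lies below 0. The software and settings that made these intensities are not given in the sources used here. Their medians and upper quantiles differ between arrays, so the deposited values were taken as not normalised between arrays. The authors also deposited 1 table per time point that combines the replicates of each fatty acid, made with Rosetta Resolver per the file headers, with version and settings not given in the sources used here. Per the file headers these tables hold a linear ratio, its log10 and a p-value per probe set, and the method behind the authors' p-value is not given in the sources used here. The file headers do not name the direction of the authors' ratio. It was taken as CLA over LA because the log ratios correlated positively across genes with CLA minus LA at each time, so the sign of that correlation is no separate evidence. The 6 columns of combined intensities in these tables, whose fatty acid the headers do not name, were not used. The ratio tables were used only for comparison, with the authors' p-values adjusted by Benjamini-Hochberg over the genes tested.

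The intensities were quantile normalised over the 11 arrays, values below 0 were set to 0, and log2(value + 1.84) was taken, the offset being the 25th percentile of all values. Log2 differences are on that scale, which understates the change of dim genes. Of 45101 probe sets, 64 array controls were left out, and probe sets with a mean above 7.81 (the 40th percentile) were kept, leaving 26627. Probe sets were named through the platform annotation. Of the 45037 other than controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol were counted as genes. Of these, 34741 matched by Entrez ID a table of current mouse genes of the assembly GRCm38.p6, used for names only, 204 kept the annotation's own symbol, and the match changed no symbol. The probe set with the highest mean stood for a gene, which gave 12428 genes, 5746 of them with several passing probe sets. Transcript length and base composition were not tested.

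Differences were tested in limma with 1 mean per group (6 groups, all 11 arrays in 1 fit, 5 residual and 6.17 prior degrees of freedom), an intensity trend in the prior spread, and Benjamini-Hochberg adjustment at 0.05 over all genes. The contrasts were CLA minus LA at each time, the mean of these 3 differences, the change of the difference over time (an F test and pairwise terms), and 12 h minus 8 h in each fatty acid. Errors of log2 differences are standard errors from this fit, and errors of intensities are SDs over arrays. The single LA array of 4 h was assumed to vary like the other groups. A gene was taken to be at background in a group when all arrays of that group lay at or below 8.89, the 95th percentile of 27 unspiked bacterial control probe sets. Its difference is then given as at least N-fold, the bright group's mean over the dim group's mean of the higher of that level and the measured value per array, in log2 space.

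Gene lists were tested with camera (preset correlation 0.01, and again with an estimated one) and fry, adjusted over the lists within a contrast. The 22 lists covered the integrated stress response, aminoacyl-tRNA synthetases, amino acid transporters, ER chaperones, inflammatory genes, prostaglandin synthesis, NRF2 targets, heat shock proteins, immediate early genes, adipogenic transcription factors, fatty acid and triglyceride synthesis, lipid uptake and droplets, fatty acid oxidation, cholesterol synthesis, glucose uptake and insulin signalling, adipokines, the respiratory chain, glycolysis and hypoxia, extracellular matrix, cell cycle, apoptosis and p53 targets, and autophagy. The 6 marker lists covered adipocytes, preadipocytes and fibroblasts, macrophages, endothelial cells, skeletal muscle, and osteoblasts and chondrocytes. List members below the filter, or without a probe set named for them alone, were not analysed here.

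The tests, lists, contrasts and the rule for named genes were fixed before the data were examined. The rule took, per time and for the averaged contrast, the 10 largest called increases and 10 largest called decreases with the arrays of each fatty acid apart (for the averaged contrast, with the same sign at all 3 times), or the 5 smallest p-values where fewer than 5 genes passed. It also took up to 4 members of each list with the smallest p in the averaged contrast, and 20 genes of stress, inflammation and fat storage whatever their values.

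Alternatives fixed in advance were the values as deposited, scaling to the same median, another offset, no filter or a filter at the 60th percentile, no intensity trend, a replicate block, the mean of a gene's probe sets, only the arrays compared, a difference of at least 1 on the log2 scale, and each array left out in turn. Cyclic loess, the mean without 4 h or without 12 h, and the log2 median intensity of each array as a covariate were added after seeing the data. The fit was tested on simulated data of 12774 genes with known changes. At a true log2 difference of 0.5, 1 and 2 it recovered 17.2%, 44.6% and 80.0% of changed genes at 4 h, 28.1%, 53.8% and 81.7% at 8 h, 28.1%, 58.5% and 83.3% at 12 h, and 56.3%, 76.9% and 98.3% in the averaged contrast. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.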

Results

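Transcript levels were measured in 3T3-L1 cells, a mouse fibroblast line that can be driven to become adipocytes and is labelled here as preadipocyte culture. The cells were given t10c12 CLA (conjugated linoleic acid with a trans and a cis double bond at carbons 10 and 12) or, as the control, linoleic acid (LA), an isomer whose double bonds are both cis and are not conjugated. RNA was taken after 4, 8 or 12 h and hybridised to 1-colour Affymetrix arrays, and the labels give no dose. The question was which transcripts differ between cells given CLA and cells given LA at each time. The 11 arrays comprised 1 LA and 2 CLA arrays at 4 h, 2 LA and 2 CLA arrays at 8 h, and 2 LA and 2 CLA arrays at 12 h. Another LA array at 4 h, which the submitters' design text implies, was not analysed here. The labels call the replicates biological but do not say that they are separate cultures, so p-values measure only the spread between these samples, which may be technical.

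The deposited intensities were not scaled between arrays. Their medians over 45101 probe sets were 18.9 in the LA array at 4 h, 14.4 and 15.1 in the CLA arrays at 4 h, 13.9 and 14.3 in LA at 8 h, 20.1 and 12.8 in CLA at 8 h, 11.6 and 10.6 in LA at 12 h, and 14.7 and 15.8 in CLA at 12 h. Between 18.7% and 21.5% of an array's values lay at or below 0. Replicates of a group correlated across genes at Pearson r = 0.970 to 0.978, and no pair shared identical values. After quantile normalisation, the leading principal component (35.6% of the variance) placed the 4 h arrays between −43.0 and −38.2 and both LA arrays of 12 h apart from all others, at 48.7 and 48.8. The CLA arrays of 12 h lay at 5.45 and 16.4, within reach of the CLA arrays of 8 h at −15.2 and 8.21. The small number of arrays limits the precision of every value below. Without scaling, the median log2 difference of all genes between CLA and LA was −0.28 at 4 h, 0.07 at 8 h and 0.28 at 12 h, against −0.02, −0.04 and −0.15 after quantile normalisation.

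**Figure D1:**
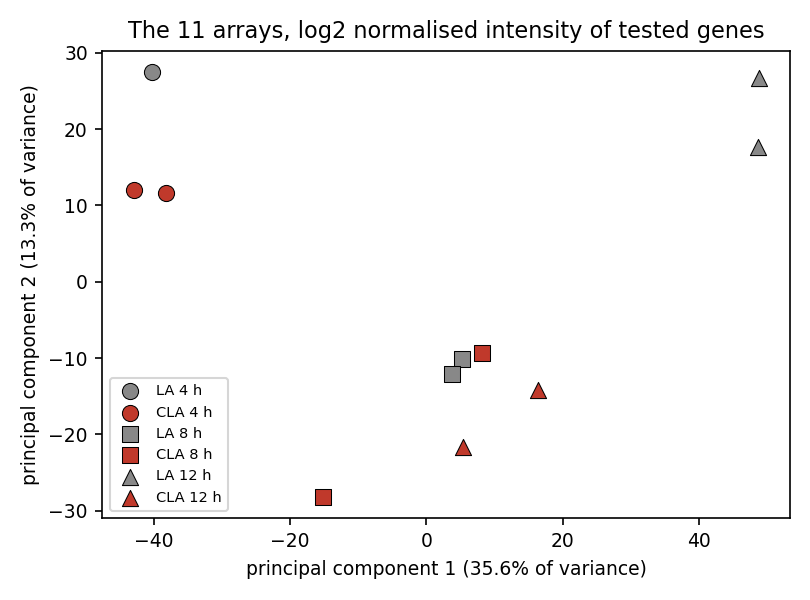
Position of the 11 arrays on the leading pair of principal components of the normalised log2 intensities (PC1, 35.6% of the variance, on the x axis and PC2, 13.3%, on the y axis), with LA in grey, CLA in red, and circles, squares and triangles for 4, 8 and 12 h. Each point is 1 array, and the LA arrays of 12 h sit at the right, at 48.7 and 48.8 on PC1.

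Averaged over the 3 times, transcripts of Angptl4, Pdk4, Cpt1a and Plin2 were higher in cells given CLA than in cells given LA. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, was 1.42-fold higher (log2 difference 0.51 ± 0.08 SE, adjusted p = 0.0148). Pdk4, a kinase that holds back pyruvate oxidation, was 1.46-fold higher (0.55 ± 0.09, adjusted p = 0.0164). Cpt1a, which carries long-chain fatty acids toward mitochondrial oxidation, was 1.24-fold higher (0.31 ± 0.05, adjusted p = 0.0148), and Plin2, a lipid droplet coat protein, rose by 0.30 ± 0.05 (adjusted p = 0.0186). Each of these genes was higher with CLA at all 3 times. Normalised intensity of Angptl4 was 1845 in the 1 LA array at 4 h, 1398 ± 20.5 (SD, n = 2) in LA at 8 h and 1760 ± 4.30 in LA at 12 h, against 2518 ± 26.5, 2410 ± 476 and 2184 ± 340 in CLA.

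Lower with CLA were Hk2, Ccnd1, Mcm5, Fosl1 and Phlda1. Hk2, a hexokinase that starts glycolysis, fell by 0.65 ± 0.10 (adjusted p = 0.0148), from a normalised intensity of 1174, 922 ± 22.0 and 643 ± 65.8 in LA at 4, 8 and 12 h to 804 ± 55.9, 579 ± 144 and 396 ± 42.3 in CLA. Ccnd1 (cyclin D1, which drives entry into S phase) fell by 0.37 ± 0.06 (adjusted p = 0.0148), and Mcm5, part of the replicative helicase, fell by 0.47 ± 0.08 (adjusted p = 0.0177). Fosl1, a subunit of the AP-1 transcription factor, fell by 0.91 ± 0.15 (adjusted p = 0.0164), and Phlda1 fell by 0.64 ± 0.08 (adjusted p = 0.0148). Each of these genes was lower with CLA at all 3 times. Among the genes with the largest called differences, most were dim, such as Dusp18 (log2 difference 1.70) and Zap70 (−1.75).

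Signs of RNA quality and a hybridisation control moved with fatty acid too, at each time and so beside the gene groups of every comparison of CLA with LA. The GAPDH 3' to 5' ratio was higher in every LA array than in every CLA array of the same time, at 1.077 against 0.888 and 0.928 at 4 h, 1.011 and 1.020 against 0.893 and 1.008 at 8 h, and 0.983 and 1.18 against 0.884 and 0.954 at 12 h. The same held for the actin 3' to 5' ratio, at 1.75 against 1.47 and 1.69 at 4 h, 1.63 in both LA arrays against 1.32 and 1.54 at 8 h, and 1.55 and 1.59 against 1.49 and 1.31 at 12 h. The signal of the Cre hybridisation control was 6953 to 8235 in the 5 LA arrays and 6153 to 6548 in the 6 CLA arrays.

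**Figure D2:**
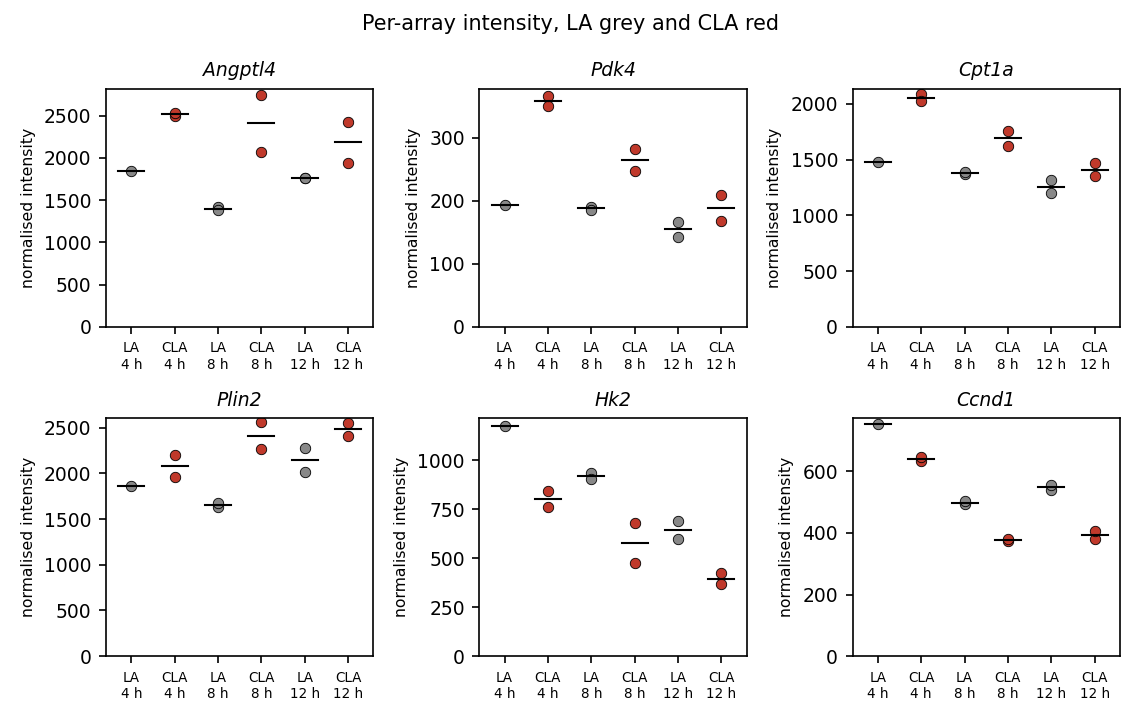
Normalised intensity (y axes, linear) of Angptl4, Pdk4, Cpt1a, Plin2, Hk2 and Ccnd1 at 4, 8 and 12 h (x axes), with 1 point per array (LA grey, CLA red) and bars at the group means. Angptl4 went from 1398 in LA to 2410 in CLA at 8 h, and Hk2 from 922 to 579.

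Of 22 gene lists fixed in advance, 5 shifted in the averaged contrast by camera, which compares a list's mean test statistic with that of all other genes. The fatty acid oxidation list shifted up (median log2 difference 0.08). In that list 4 of 14 measured members rose (Angptl4, Pdk4, Cpt1a and Acadl) and 1 fell (Hadh, by 0.22, named after its value was seen), or 5 and 1 adjusted over the list alone. By the roles given above, Angptl4 and Pdk4 are not themselves enzymes of fatty acid oxidation. Of the other called members, Cpt1a and Acadl rose and Hadh fell. The list's adjusted p was 0.0171, and the call was lost at adjusted p = 0.715 with an estimated correlation. Cholesterol synthesis genes also shifted up (median 0.12), with 3 of 16 higher (Idi1 0.53, Hmgcs1 0.26 and Msmo1 0.21) and none lower, or 4 and 1 adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.523 with an estimated correlation). Glycolysis and hypoxia genes shifted down (median −0.15), with 3 of 13 lower (Hk2, Hk1 and Pgk1), or 8 adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.781 with an estimated correlation). Immediate early genes shifted down (median −0.17), with 3 of 21 lower (Fosl1, Jund and Dusp4), or 8 adjusted over the list alone (adjusted p = 0.00433, and adjusted p = 0.715 with an estimated correlation). Cell cycle genes shifted down (median −0.23), with 2 of 21 lower (Ccnd1 and Mcm5), or 3 adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.601 with an estimated correlation). With each array scaled to the same median, the fatty acid oxidation (adjusted p = 0.201), cholesterol synthesis (0.201) and cell cycle (0.0528) lists no longer passed. Without 4 h in the mean, these 3 lists (0.0595, 0.104 and 0.104) and glycolysis and hypoxia (0.104) did not pass, and without CLA replicate 2 of 8 h the first 3 did not (0.0592, 0.0592 and 0.0754). The glycolysis and hypoxia call also ended with the mean of a gene's probe sets (0.147), with a replicate block within each time (0.0862) and without CLA replicate 2 of 4 h (0.0541) or LA replicate 2 of 8 h (0.0546). The cell cycle call ended with the mean of a gene's probe sets too, and the cholesterol synthesis call ended without 12 h in the mean. Over all alternatives the adjusted p ran from 5.43e-04 to 0.201 for fatty acid oxidation, 0.00687 to 0.201 for cholesterol synthesis, 0.00593 to 0.11 for cell cycle and 0.00252 to 0.147 for glycolysis and hypoxia. By fry, which asks whether a list's genes move one way and not how they stand against other genes, the cell cycle (adjusted p = 0.00615) and cholesterol synthesis (0.0498) lists passed, and the fatty acid oxidation (0.0859), glycolysis and hypoxia (0.0859) and immediate early (0.0677) lists did not.

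**Figure D3:**
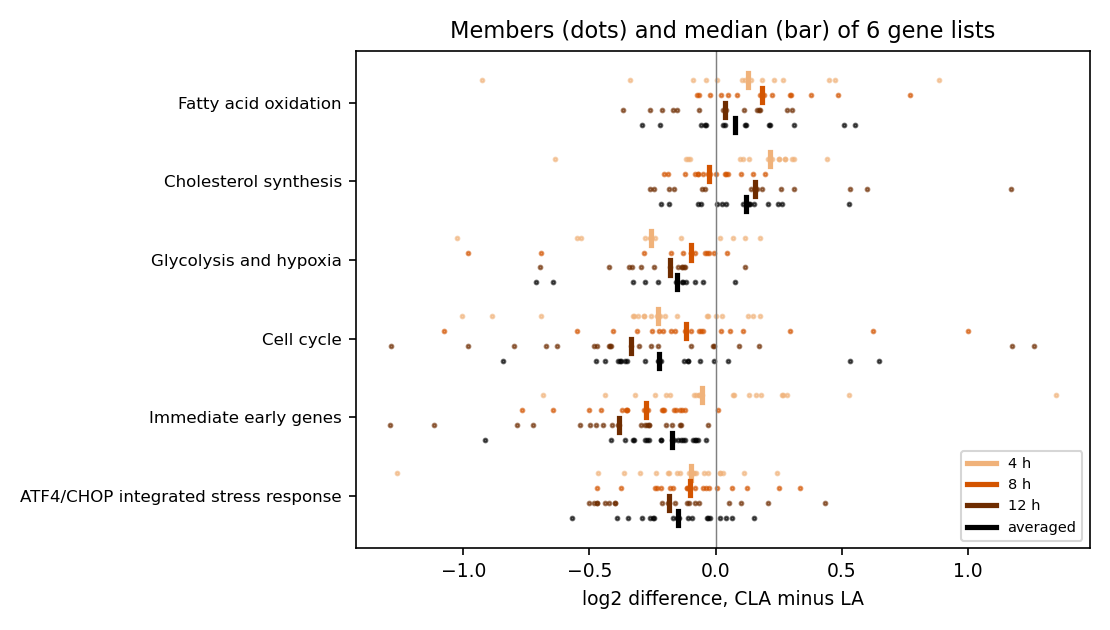
Log2 difference, CLA minus LA (x axis), of the measured members of 6 gene lists (y axis), with colours for 4, 8 and 12 h and the average over time. Each dot is 1 gene and each bar the list's median, which in the averaged contrast was 0.08 for fatty acid oxidation and −0.17 for immediate early genes.

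The other 17 lists did not pass camera in the averaged contrast (adjusted p = 0.182 to 0.995), but single members passed. The inflammatory list passed fry (median −0.13, against −0.07 for all genes, adjusted p = 0.0278). Of 20 genes of the integrated stress response 3 fell, or 4 adjusted over the list alone, among them Chac1 by 0.39 and Phgdh by 0.26. Of 10 amino acid transporters 3 fell and 1 rose, or 4 and 1 adjusted over the list alone, with Slc7a5 falling by 0.35 and Slc38a2 rising by 0.24. Of 14 aminoacyl-tRNA synthetases none passed, and 3 were lower adjusted over the list alone. The endoplasmic reticulum (ER) chaperone list had 4 higher of 20 in either adjustment, among them Dnajc3 (0.36) and Hsp90b1 (0.35). The heat shock list of 11 had Hsp90aa1 higher (0.53) and Hspb1 lower (−0.58), or 2 and 2 adjusted over the list alone. Of 14 apoptosis and p53 target genes, Mdm2 (0.30) and Trp53inp1 (0.56) rose, or 4 higher and 4 lower adjusted over the list alone. Of 20 inflammatory genes, Socs3 fell by 0.35 and Birc3 by 0.25, or 6 lower adjusted over the list alone. Fatty acid and triglyceride synthesis had 2 higher of 16 in either adjustment, Elovl6 (0.34), which lengthens saturated fatty acids, and Scd2 (0.27), a stearoyl-CoA desaturase.

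Extracellular matrix genes had 2 higher and 2 lower of 21, or 3 and 5 adjusted over the list alone, led by Postn (0.64 ± 0.13). The glucose uptake and insulin signalling list of 12 had Pik3r1 (0.36) higher and Hk2 and Slc2a1 (−0.23) lower in either adjustment. In the respiratory chain list of 22, Uqcrfs1 rose by 0.18 and Cyc1 fell by 0.16, or 1 higher and 2 lower adjusted over the list alone. Tkt (−0.27) was the 1 of 14 NRF2 targets, Cebpd (−0.42) the 1 of 12 adipogenic transcription factors, and Plin2 the 1 of 11 genes of lipid uptake, droplets and lipolysis that passed, in either adjustment. Angptl4 was the 1 of 5 adipokine genes that passed, with 1 more, lower, adjusted over the list alone. None of 6 prostaglandin synthesis genes passed, with 2 lower adjusted over the list alone, and none of 12 autophagy genes passed in either adjustment. Several genes of stress and fat storage that were named in advance did not pass. The 95% interval of the log2 difference was −0.26 to 0.04 for Ddit3 (CHOP), −0.09 to 0.17 for Atf4, −0.12 to 0.07 for Hspa5 (BiP), −0.01 to 0.29 for Scd1 and −0.07 to 0.27 for Fabp4, while Fasn lay at −0.15 (−0.29 to −0.02) without passing after adjustment.

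In all, limma called 896 of 12428 genes in the averaged contrast, 517 higher and 379 lower, with 3338 at an unadjusted p under 0.05, and 25 of the 896 differed by at least 1 on the log2 scale. With each array scaled to the same median the calls were 419 higher and 69 lower, and with the values as deposited 16 higher and 2 lower. The count fell to 1 without an intensity trend in the spread and to 0 without LA replicate 1 of 8 h, and the adjusted p over all alternatives ran from 0.00272 to 0.101 for Angptl4, 0.00589 to 0.101 for Pdk4, 0.00511 to 0.189 for Cpt1a and 0.00148 to 0.111 for Hk2. With the log2 median intensity of each array as a covariate, a setting chosen after the data were seen, 538 genes were called, 525 of the 896 among them. Angptl4, Pdk4, Cpt1a, Plin2, Hk2 and Ccnd1 still passed (adjusted p = 0.0150 to 0.0218), and over all alternatives the adjusted p ran from 0.00754 to 0.252 for Plin2 and from 0.00279 to 0.318 for Ccnd1. Of the other genes named above for this contrast, Dnajc3, Elovl6, Hspb1, Hk1, Pgk1, Dusp4, Birc3, Uqcrfs1 and Cyc1 lost their call (0.0527 to 0.0680) at differences close to those without it, such as 0.34 for Elovl6 (0.34 before), −0.54 for Hspb1 (−0.58) and 0.30 for Dnajc3 (0.36). Their adjusted p over all alternatives lay between 0.0103 and 0.955. Without the 12 h arrays in the mean, 9 genes were called, and Angptl4 (0.61), Pdk4 (0.68) and Cpt1a (0.38) had adjusted p = 0.0535. In that setting Hk2 (adjusted p = 0.111), Plin2 (0.116), Phlda1 (0.117), Ccnd1 (0.169), Acadl (0.190) and Fosl1 (0.272) did not pass either.

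At 4 h, where LA had 1 array, Dnajc12, a co-chaperone of the HSP40 family, was higher with CLA by 2.16 ± 0.22 on the log2 scale (adjusted p = 0.00295), with a normalised intensity of 15.0 in the LA array and 73.0 ± 4.98 (SD, n = 2) in CLA. Several other genes were at background in the LA array, so that their difference is a lower bound. Ptpdc1 was at least 5.99-fold higher with CLA (adjusted p = 3.54e-05), Zfp691 at least 4.47-fold (0.00930), Tdp1, a DNA repair enzyme, at least 4.51-fold (0.0211) and Fam160a1 at least 2.96-fold (1.26e-04). Csf1r, the receptor for macrophage colony-stimulating factor, was lower by a log2 difference of −3.10 ± 0.36 (adjusted p = 0.00806), from 1171 in the LA array to 138 ± 41.9 in CLA. Lower transcripts also included Zap70 (−3.21), Pik3cd (−2.31), Lgals2 (−2.54) and Dennd6b (−2.30). Pdk4, Cpt1a and Angptl4 had the sign of the averaged contrast without passing, with Pdk4 at 0.89 ± 0.17 (adjusted p = 0.0832), Cpt1a at 0.47 ± 0.10 (0.0916) and Angptl4 at 0.45 ± 0.15 (0.365).

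Camera placed 4 lists apart at 4 h, none with a member past the threshold over all genes, and each had an adjusted p of 0.0475. Fatty acid and triglyceride synthesis (16 genes, none adjusted over the list alone) had a median of 0.14, and −0.10 with the values as deposited (adjusted p = 0.777 with an estimated correlation). Fatty acid oxidation (14 genes, 3 higher and 1 lower adjusted over the list alone) had a median of 0.13, and −0.12 with the values as deposited (adjusted p = 0.777 with an estimated correlation). Cholesterol synthesis (16 genes, 4 higher and 1 lower adjusted over the list alone) had a median of 0.22, and −0.05 with the values as deposited (adjusted p = 0.678 with an estimated correlation). Glycolysis and hypoxia (13 genes, 4 lower adjusted over the list alone) had a median of −0.26 (adjusted p = 0.943 with an estimated correlation). With the values as deposited the median of all genes at 4 h was −0.28, so the list medians of −0.10, −0.12 and −0.05 still lay above it. The number of lists apart was 0 under either other scaling. It was also 0 with cyclic loess, with the mean of a gene's probe sets and with a replicate block, shared or within each time. Over 21 alternatives, the 4 lists kept direction and call in 24 of 84 values and lost the call in 60.

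The 4 h count was 36 genes, 15 higher and 21 lower, with 1130 at an unadjusted p under 0.05, and 15 higher and 43 lower with the values as deposited. In 33 of the 36 genes the LA array lay outside the range of all 10 other arrays, as it did in 23.9% of all genes, and in 10 of the 36 a group was at background. Ptpdc1 rests on 1 probe set, since its other probe sets gave 0.25, 0.95, −0.06 and −0.45. The count was 0 when only the 4 h arrays entered the fit, 8 without an intensity trend and 15 and 17 without CLA replicate 1 or 2.

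At 8 h no gene passed. Among the smallest p-values were those of Angptl4, Plin2 and Ppara, with Angptl4 at a log2 difference of 0.77 ± 0.12 (adjusted p = 0.275), Plin2 at 0.54 ± 0.09 (0.275) and Ppara, a receptor that fatty acids activate, at least 4.18-fold above LA (0.169). Ppara was at background in LA, at 6.95 ± 0.43 (SD, n = 2), against 37.4 ± 6.0 in CLA. Crim1 (−0.94, adjusted p = 0.281), Phlda1 (−0.69, 0.386), Plpbp (−0.45, 0.386) and Hunk (−2.55, 0.538) were lowest in p among genes below LA, and Hk2 lay at −0.69 ± 0.15 (0.684).

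As lists, immediate early genes shifted down at 8 h (median −0.28 over 21 genes, adjusted p = 1.04e-06), with no member past the threshold, also adjusted over the list alone. The fatty acid oxidation list, Angptl4 and Pdk4 included, shifted up (median 0.18 over 14 genes, adjusted p = 6.70e-06), with no member past the threshold over all genes and 5 higher adjusted over the list alone. Both calls were lost at adjusted p = 0.607 with an estimated correlation. The count of 0 came from limma with 495 genes at an unadjusted p under 0.05. It was 14 without the filter on dim probe sets, 8 without CLA replicate 2 of 8 h and 2 with a replicate block within each time.

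At 12 h, single genes of chaperones, sterol synthesis and p53 targets were among those higher with CLA. Their lists did not pass camera (adjusted p = 0.262 for ER chaperones, 0.715 for heat shock proteins, 0.0593 for cholesterol synthesis and 0.335 for apoptosis and p53 targets). By fry, cholesterol synthesis and apoptosis and p53 targets passed at 12 h (both adjusted p = 0.0307), as did the cell cycle (0.00468), inflammatory (0.0307), integrated stress response, NRF2 target, immediate early and respiratory chain lists (each 0.0489), all 6 with medians below 0. The median of all genes at 12 h was −0.15, which fry does not take into account. A list median below 0 therefore does not by itself set a list apart from other genes. Camera placed the apoptosis and p53 list upward, with a mean of 0.09 but a median of −0.08. Hsp90aa1, a cytosolic chaperone, was 2.28-fold higher (log2 difference 1.19 ± 0.16, adjusted p = 0.00127), and Dnajc3, an ER co-chaperone, 2.02-fold (1.02 ± 0.14, 0.00127). Idi1, an enzyme of isoprenoid and sterol synthesis, was 2.25-fold higher (1.17 ± 0.16, 0.00127), Trp53inp1, which p53 induces, 2.40-fold (1.26 ± 0.16, 0.00103), and Postn, a matrix protein, 2.13-fold (1.09 ± 0.21, 0.00698). Lower transcripts included Fosl1 at −1.29 ± 0.25 (0.00611), Phlda1 at −0.90 ± 0.13 (0.00147), Mcm5 at −0.80 ± 0.13 (0.00319), Hk2 at −0.70 ± 0.15 (0.0116) and Ccnd1 at −0.48 ± 0.09 (0.00562). In each of these genes both CLA arrays lay on the same side of both LA arrays. That held for all 1177 higher and 1171 lower genes called at 12 h, so it adds nothing to their call.

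By list, only immediate early genes passed camera at 12 h (median −0.38, and 0.08 against an all-gene median of 0.28 with the values as deposited, adjusted p = 0.0206). Of its 21 genes 4 were lower, among them Fosl1 and Dusp4 (−0.47, or 0.0048 with the values as deposited), or 10 adjusted over the list alone. The call was lost at adjusted p = 0.898 with an estimated correlation. It also ended for immediate early genes with the filter at the 60th percentile (adjusted p = 0.0571), without LA replicate 2 of 12 h (0.0543) and without CLA replicate 1 of 12 h (0.0843), and the adjusted p ran from 0.00223 to 0.0843 over the alternatives. Cholesterol synthesis had 3 of 16 genes higher in either adjustment (Idi1, Hmgcs1 0.60 and Msmo1 0.31, list adjusted p = 0.0593). Of 20 ER chaperone genes 4 were higher and 1 lower in either adjustment, with Hsp90b1 (0.62) and Pdia3 (0.59) higher. Of 11 heat shock genes 3 were higher in either adjustment, among them Dnaja1 (0.76). Of 14 apoptosis and p53 target genes 5 were higher and 2 lower, or 5 and 3 adjusted over the list alone, with Mdm2 at 0.59, Ccng1 at 0.63 and Bcl2l1 at −0.51 (0.47 as the mean of its probe sets). Of 21 cell cycle genes 7 were lower, or 9 lower and 2 higher adjusted over the list alone.

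Inflammatory genes went both ways at 12 h, with 2 higher and 2 lower of 20 in either adjustment. Il6 (0.51 ± 0.14, adjusted p = 0.0321) and the chemokine Ccl2 (0.42 ± 0.12, 0.0323) were higher, but not with each array scaled to the same median (0.0966 and 0.350). Over the alternatives, the adjusted p ran from 0.000987 to 0.653 for Il6 and from 0.00224 to 0.527 for Ccl2. The feedback inhibitor Socs3 (−0.54) and the NF-kB subunit Relb (−0.61) were lower. Among genes of fat cells, Pparg, the main regulator of adipogenesis, was lower (−1.51, adjusted p = 0.0124) at low intensity (43.7 ± 11.2 in LA and 13.9 ± 0.83 in CLA). Cebpd was lower (−0.67), Scd2 (0.39) and Elovl6 (0.81) were higher, and Lpl was higher (0.29, or −0.04 with each array scaled to the same median). Not passing were Ddit3 (95% interval −0.19 to 0.29), Atf4 (−0.10 to 0.30), Hspa5 (−0.06 to 0.23), Xbp1 (−0.27 to 0.05), Fasn (−0.41 to 0.02), Fabp4 (−0.10 to 0.45) and Cpt1a (−0.01 to 0.34). Wider intervals held for Slc2a4 (−0.56 to 1.62), Trib3 (−1.11 to 0.15), Ptgs2 (0.08 to 0.80, adjusted p = 0.0801), Srebf1 (−0.99 to −0.11, 0.0780) and Cebpa (−2.42 to −0.15, 0.102).

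The 12 h calls numbered 2348 of 12428 genes, 1177 higher and 1171 lower, with 4448 at an unadjusted p under 0.05. At least 1 on the log2 scale were 353 higher and 64 lower. The split was 946 higher and 367 lower with each array scaled to the same median and 1925 higher and 11 lower with the values as deposited. Of the 2348 genes, 1227 and 1182 respectively were also called in the same direction under those scalings. A group was at background in 26 of the 2348, among them several of the largest differences, such as Ly6g6g (at least 2.90-fold higher) and Srcin1 (at least 3.65-fold lower). Other probe sets of the called genes had the same sign in 2542 of 3010 cases and the opposite sign with an unadjusted p under 0.05 in 50.

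**Figure D4:**
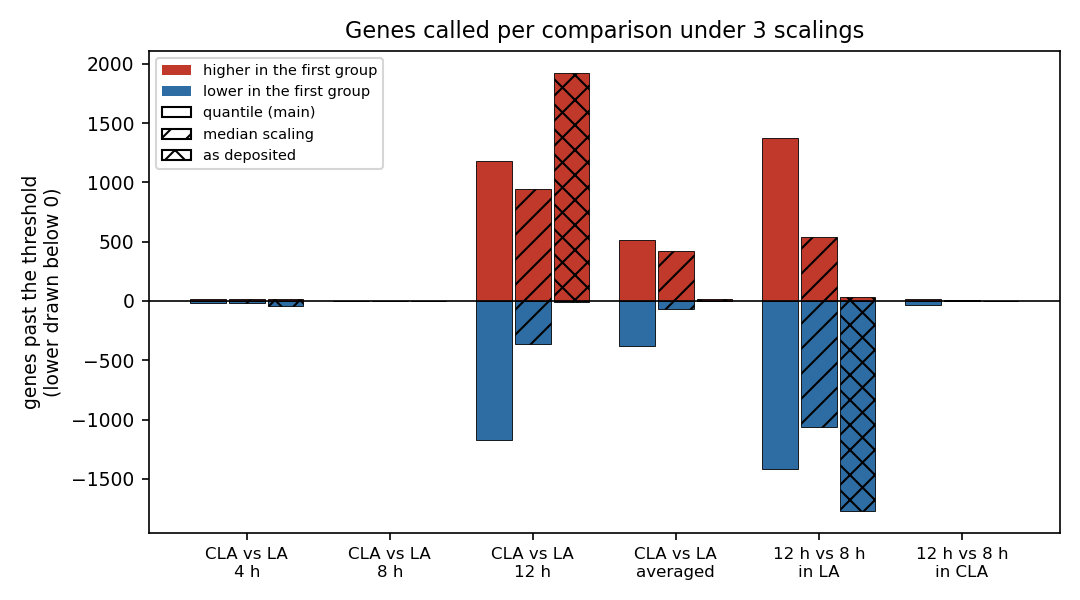
Genes called (y axis, number of genes, higher above 0 in red and lower below 0 in blue) in each comparison (x axis) under quantile normalisation, scaling to the same median and the values as deposited. At 12 h the bars hold 1177 higher and 1171 lower genes under quantile normalisation and 1925 and 11 with the values as deposited.

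Median intensity and the signal of the transferrin receptor control set both LA arrays of 12 h apart, alongside the gene groups named for 12 h. The transferrin receptor control reads a mouse transcript, so its signal can follow expression and is not a measure of array quality alone. Both LA arrays of 12 h had the lowest median intensities, 11.6 and 10.6 against 12.8 to 20.1 in the others, and the lowest signal of the transferrin receptor control, 8.49 and 9.15 against 21.1 to 54.9. Their GAPDH 3' to 5' ratios, 0.983 and 1.18, and actin ratios, 1.55 and 1.59, lay above those of both CLA arrays of 12 h (0.884 and 0.954 for GAPDH, 1.49 and 1.31 for actin). Over all other arrays these ratios ran from 0.884 to 1.08 and from 1.31 to 1.75. The pyruvate carboxylase ratio was 4.06 and 5.48, against 2.72 and 4.15 in CLA at 12 h. Across the 2348 genes, which are not independent replicates, the 12 h difference correlated at Pearson r = 0.759 and Spearman rho = 0.815 with the difference between the 2 CLA arrays of 8 h, whose medians were 20.1 and 12.8, and at r = 0.219 across the genes not called. Across the called genes the same r was 0.0613 for the CLA pair of 4 h and −0.191 for the LA pair of 8 h.

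With the log2 median intensity of each array again as a covariate, 159 genes were called at 12 h. The values then were 0.83 for Hsp90aa1 (adjusted p = 0.0608), 0.85 for Idi1 (0.0608), −0.48 for Ccnd1 (0.0830) and −0.35 for Hk2 (0.323), while Hmgcs1 (0.54, 0.0455), Mdm2 (0.41, 0.0312) and Pdia3 (0.61, 0.0293) passed. None of the 10 genes named at the start of the 12 h comparison passed (adjusted p = 0.0531 to 0.323), with Postn at 0.64 (0.285), Fosl1 at −0.93 (0.204) and Trp53inp1 at 1.09 (0.0531). Il6 lay at 0.12 (0.653) and Pparg at −1.07 (0.301), neither past the threshold. Over the alternatives, the adjusted p ran from 2.11e-05 to 0.0608 for Hsp90aa1, from 8.75e-05 to 0.0608 for Idi1, from 0.00296 to 0.88 for Ccnd1, from 0.00197 to 0.338 for Hk2, from 0.000163 to 0.127 for Hmgcs1, from 8.39e-05 to 0.349 for Mdm2 and from 5.69e-05 to 0.411 for Pdia3. It ran from 7.81e-05 to 0.285 for Postn, from 0.00227 to 0.204 for Fosl1, from 9.05e-05 to 0.0531 for Trp53inp1 and from 0.00852 to 0.301 for Pparg. The count was 713 without LA replicate 2 of 12 h, 1037 without LA replicate 1 and 1002 without CLA replicate 1 of 12 h.

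**Figure D5:**
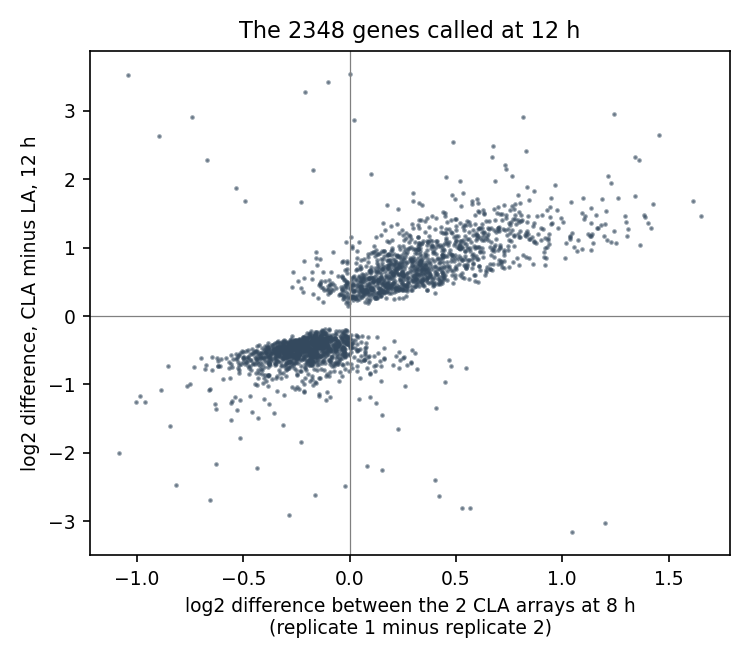
Log2 difference of CLA minus LA at 12 h against the log2 difference between CLA replicate 1 and replicate 2 of 8 h, with 1 point per gene for the 2348 genes called at 12 h. The points rise together, with Pearson r = 0.759 across genes.

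The difference between CLA and LA itself changed over time for 141 genes by limma's F test of the interaction. That count was 2 with the log2 median intensity of each array as a covariate, 4 without an intensity trend, 13 with the mean of a gene's probe sets, 3 to 728 with single arrays left out and 772 with the values as deposited. Between 8 h and 12 h it rose for 141 genes and fell for 6, of which 145 were called at 12 h. Their median log2 difference was 0.97 at 12 h and 0.06 at 8 h, and the median change from 8 h to 12 h was −1.02 in LA and −0.10 in CLA. The genes were picked on the gap between these differences in the same arrays. The gap between the medians and the many calls at 12 h therefore follow in part from that choice and are no separate evidence. Among named genes, Hmgcs1 (F test adjusted p = 0.0373), Pdia3 (0.0283) and Ccng1 (0.0497) had a difference that depended on time, and Ppara (0.0162) turned from above LA at 8 h to −1.59 at 12 h. Between 4 h and 8 h it changed for 4 genes, Ptpdc1, Fam160a1, Fbxo36 and Dnajc12, of which Fbxo36 was named after its value was seen. Across all genes the differences at 4 h and 8 h correlated at r = 0.0366, those at 4 h and 12 h at 0.00940 and those at 8 h and 12 h at 0.202. No gene was called in the same direction at 4 h and 12 h, and 2 were called in opposite directions.

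From 8 h to 12 h in cells given LA, transcripts of the chemokine Cxcl5 fell by 1.73 (adjusted p = 8.19e-05), of Ncl (nucleolin) by 1.22, of Ccl2 by 0.93 and of Lpl by 0.55, while Asns, an asparagine synthetase, rose by 0.77, Shmt2 by 0.89, Slc7a5 by 0.72 and Phgdh by 0.58. These changes rest on the LA arrays of 12 h, which had the lowest median intensities. With the log2 median intensity of each array as a covariate, 796 of 2787 called genes in LA stayed called in the same direction. In cells given CLA, Cxcl5 fell by 1.51 (adjusted p = 3.44e-04), Sned1 by 1.11 (0.00175), Pdgfra by 0.50 (0.0150), Sox9 by 0.91 (0.0275) and Lpl by 0.26 (0.0436). Tagln rose in CLA by 0.95 (0.00921), Myl9 by 0.92 (0.0150) and Actg2 by 1.44 (0.0201), and in LA they rose by 0.90, 0.86 and 1.39. Genes in these sentences outside the rule for named genes were taken from the smallest p-values of each comparison after these were seen.

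The counts were 2787 in LA, 1372 higher and 1415 lower, and 53 in CLA, 19 higher and 34 lower, with 4641 and 1277 at an unadjusted p under 0.05. In LA the split was 541 higher and 1067 lower with each array scaled to the same median, and 32 higher and 1770 lower with the values as deposited, where the median of all genes was −0.19 against 0.13. In CLA the splits were 4 and 3 and, with the values as deposited, 0 and 1. Changed in both in the same direction were 46 genes, 18 higher and 28 lower, where independent lists would share 2.10 and 3.87. That more genes passed in LA is not itself a test of a difference, and the interaction above gave 147 genes. The LA arrays of 12 h enter both the LA change and the 12 h comparison, which correlated across genes at r = −0.719, against −0.498 in 20 simulations without effects, with a covariance of −0.226 against −0.0729. Higher with CLA at 12 h and lower in LA over time were 1010 genes, and 537 went the other way, where independent lists would share 134 and 129. The shared arrays enter the comparisons with opposite signs, so part of that excess is built in, as the simulated r of −0.498 shows. Independent lists are therefore not a fair baseline here, and the size of the built-in part of the overlap was not tested.

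The headers of the authors' deposited table do not name the direction of its ratio, which was taken as CLA over LA because its log ratios correlated positively with the differences given here. In the authors' deposited table the ratio of CLA over LA for Angptl4 was 1.34 at 4 h, 1.64 at 8 h and 1.18 at 12 h, with Benjamini-Hochberg values of the authors' p-values of 7.4e-05, 1.9e-29 and 1.2e-04. In the authors' deposited table Pdk4 had 1.95, 1.53 and 1.31, Cpt1a 1.98, 1.26 and 1.08, and Hk2 0.767, 0.709 and 0.764 at the 3 times. For Ptpdc1 at 4 h the authors' deposited table gave 1.78 with a p-value of 0.0566. Across genes, the log2 ratios of the authors' deposited table correlated with the differences given here at r = 0.655 at 4 h, 0.679 at 8 h and 0.820 at 12 h. Signs were the same as in the authors' deposited table for 33 of 36 called genes at 4 h and 2341 of 2348 at 12 h. With the direction of the authors' deposited table turned these would be 3 and 7, so the shared sign follows from the choice of direction and is no separate evidence. After Benjamini-Hochberg adjustment the authors' deposited table held 49 higher and 61 lower genes at 4 h, 7 and 8 at 8 h, and 1652 and 957 at 12 h. Genes called in both this fit and the authors' deposited table numbered 10 at 4 h, 0 at 8 h and 1730 at 12 h, all with the same sign, where independent lists would share 0.319, 0 and 493. Both lists come from the samples of this series, so they are not independent. The overlap and the correlations are therefore no separate evidence for the calls.

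Markers of cell types other than preadipocytes showed no shift as lists in the averaged contrast. The adipocyte list had 5 of 12 members measured (median 0.07, adjusted p = 0.472), the preadipocyte and fibroblast list 10 of 12 (−0.01, 0.585), the macrophage list 6 of 10 (−0.15, 0.585), the skeletal muscle list 3 of 8 (0.16, 0.472) and the osteoblast and chondrocyte list 4 of 8 (0.01, 0.472). Of the endothelial list only Tek was measured (−0.32 ± 0.45, adjusted p = 0.677), so no set test was run. Single markers that passed in the averaged contrast were Postn, of the fibroblast list, and Csf1r (−0.87, adjusted p = 0.0264), of the macrophage list. The Csf1r value rests on 4 h, with 1 LA array (−3.10), since the difference was −0.13 at 8 h and 0.62 at 12 h, neither past the threshold, and its call ended with the log2 median intensity as a covariate (−0.85, adjusted p = 0.0540). Adjusted over the list alone, 1 fibroblast marker was higher and 1 lower, 1 macrophage marker was lower, 1 marker of osteoblasts and chondrocytes was higher, and no adipocyte or muscle marker passed. Of the adipokines, Adipoq and Lep did not reach the intensity filter, with mean intensities of 4.41 and −37.1, nor did the stress factor Atf3 at 7.73.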

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

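The test of a sample-quality axis, the covariate and cyclic loess were chosen after the array positions and the 12 h counts had been seen, while the tests of time dependence were planned. The difference between CLA and LA depended on time for 141 genes, differed between 12 h and 8 h for 147, between 12 h and 4 h for 167 and between 8 h and 4 h for 4. The count of 141 fell to 2 with the log2 median intensity of each array as a covariate and to 4 without an intensity trend, and ran from 3 to 728 with single arrays left out. Adjusted p-values of the F test for time dependence below are for genes named in the report.

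Genes whose difference between CLA and LA was called at 4 h and depended on time were Ptpdc1 (5.35e-04), Fam160a1 (5.76e-04), Dnajc12 (0.00991), 1700009N14Rik and Csf1r (both 0.0202), Dennd6b (0.0211), Lgals7 (0.0243), Zfp691 (0.0245), 1700123K08Rik and Sec14l3 (both 0.0298), Pik3cd (0.0303), Fem1a (0.0324), Tnn (0.0348), Lgals2 and Med18 (both 0.0373), Tdp1 (0.0473) and Klhdc1 (0.0482). At 8 h, where no gene was called, Ppara (0.0162), Crim1 (0.0286) and Plpbp (0.0438) had among the smallest p-values, and their difference depended on time. The differences of Pdia3 (0.0283), Hmgcs1 (0.0373) and Ccng1 (0.0497) were called at 12 h and depended on time.

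The genes called at 4 h rest on 1 LA array. In 33 of the 36 that array lay outside the range of the 10 other arrays, and in 11 it did so while both CLA arrays lay within the range of the later arrays, as in 1177 of all 12428 genes. That is fewer than would be needed if the LA array alone carried most calls and more than if it carried few. Both CLA arrays lay outside all other arrays in 6 of the 36, and in 2023 of all 12428 genes. The calls thus went with an extreme LA array far more often than with extreme CLA arrays. An odd LA array and a brief response to CLA still cannot be told apart, since 1 array gives no spread of its own. For Csf1r the LA array of 4 h lay at 1171 and the CLA arrays of 4 h at 138 ± 41.9 (SD, n = 2). That gap alone cannot tell an odd LA array from a response to CLA. No biological explanation was tested.

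Of the 2348 genes called at 12 h, 1010 were higher with CLA at 12 h and lower in LA from 8 h to 12 h, and 537 went the other way. Loss of RNA ends in LA replicate 2 of 12 h, whose GAPDH 3' to 5' ratio of 1.18 was the highest, is argued against as the whole cause, because 713 genes were called without that array, while lower RNA quality in both LA arrays of 12 h was not tested and stays open, since the ratio was also higher in LA replicate 1 (0.983) than in either CLA array (0.884 and 0.954). An intensity-dependent scaling error stays open, because cyclic loess, which kept 2279 of the 2348 calls, works like quantile normalisation and moved the called differences by a median of only 0.037 (median SE 0.14), while 1227 and 1182 were kept with scaling to the same median and the values as deposited. An axis of sample quality or cell state that also separates arrays of 1 group is a candidate explanation, since the 12 h differences correlated at r = 0.759 across the called genes with the difference between the CLA arrays of 8 h, against r = 0.219 across the genes not called. With the log2 median intensity as a covariate, 159 genes were called, the median absolute log2 difference of the 2348 went from 0.58 to 0.43 and their median SE from 0.14 to 0.16 with 4 residual degrees of freedom, and 1455 kept an unadjusted p under 0.05 with no sign turned, so calls ended through both smaller differences and larger errors, and a response to fatty acid that differs between 8 h and 12 h stays open too, since brightness and group go together at 12 h.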

How the results depend on the processing

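Cyclic loess, the brightness covariate (the log2 median intensity of each array) and the means without 4 h or 12 h were chosen after seeing the data, and the other alternatives were planned. Beside the genes counted in the report, camera placed 4, 2, 1 and 5 gene lists apart at 4 h, 8 h, 12 h and averaged over time. Named genes called at 12 h mostly kept their direction: of 1572 values of 73 named genes over 22 settings, 1103 kept direction and call, 458 lost the call and 11 turned sign. For 65 genes of the averaged contrast over 23 settings these numbers were 727, 751 and 1 of 1479, and for 20 genes of 4 h they were 293, 121 and 3 of 417. An offset at the 5th percentile gave no value because it is negative (−9.23), and no 4 h, averaged or time-dependence value exists without the single LA array of 4 h. A group was at background in 10 of the 36 genes called at 4 h, which makes their differences bounds.

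With the values as deposited, limma called 58 genes at 4 h, 18 averaged, 772 for time dependence, 1802 for 12 h against 8 h in LA and 1 in CLA, and lists numbered 0 at 4 h, 5 at 8 h and 3 averaged. Of 2346 called genes still tested, 267 turned sign at 12 h there, and the named genes among them were Slc7a5 (0.052), Ptges2 (0.025), Mt2 (0.057), Gsta4 (0.14), Dusp4 (0.0048), Plin4 (0.047), Ndufv1 (0.013) and Mcm2 (0.014), where the median of all genes was 0.28. Scaling to the same median gave 1313 genes at 12 h, 488 averaged, 264 for time dependence, 1608 in LA and 7 in CLA, lists numbered 0, 6, 2 and 2 at 4 h, 8 h, 12 h and averaged, and 19 called genes turned sign at 12 h, of those named Lpl (−0.037) and Lox (−0.092), and 2 averaged, of those named Lox (−0.020). Cyclic loess gave 256 for time dependence and 0 lists at 4 h. Without a filter, which admits dim probe sets, limma called 67 genes at 4 h, 14 at 8 h, 1298 at 12 h, 98 averaged, 73 for time dependence and 28 in CLA, and 2 lists at 12 h. The filter at the 60th percentile gave 232 for time dependence, 5 lists at 8 h and 0 at 12 h. Without an intensity trend the counts were 8 at 4 h, 1059 at 12 h, 1 averaged, 4 for time dependence, 1658 in LA and 4 in CLA. The mean of a gene's probe sets gave 435 averaged, 13 for time dependence, 21 in CLA, 0 lists at 4 h and 3 averaged, and turned the sign of 76 called genes at 12 h (2 of them called the other way), of those named Bcl2l1 (0.47), and of 28 averaged (2 called the other way). With only the arrays compared the counts were 0 at 4 h, 1464 at 12 h and 5 in CLA, while that in LA was 4064. Asking for at least 1 on the log2 scale left 417 at 12 h, 25 averaged, 91 for time dependence, 491 in LA and 8 in CLA. The mean without 12 h gave 9 genes, and the mean without 4 h gave 1417 genes and 1 list. With the brightness covariate the counts were 9 at 4 h, 159 at 12 h, 538 averaged, 2 for time dependence and 817 in LA, with 1 list at 4 h and 3 at 12 h. The cause was not tested.

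Each array was left out in turn, with a lone array in a group assumed to vary like the others. Counts ran from 15 (without CLA replicate 1 of 4 h) to 67 (without either CLA array of 12 h) at 4 h and from 0 to 8 (without CLA replicate 2 of 8 h) at 8 h. At 12 h they ran from 713 (without LA replicate 2 of 12 h) to 3263 (without CLA replicate 2 of 8 h), with 1037 without LA replicate 1 and 1002 without CLA replicate 1 of 12 h. Averaged over time they ran from 0 (without LA replicate 1 of 8 h) to 2542 (without CLA replicate 2 of 8 h), with 11 and 122 without CLA replicate 2 or 1 of 4 h, 123 and 428 without LA replicate 2 or 1 of 12 h, 155 without LA replicate 2 and 474 without CLA replicate 1 of 8 h, and 516 without CLA replicate 1 of 12 h. Time dependence ran from 3 (without LA replicate 2 of 8 h or CLA replicate 2 of 4 h) to 728 (without CLA replicate 1 of 8 h). The change from 8 h to 12 h in LA ran from 798 (without LA replicate 2 of 8 h) to 3502, with 1099 without LA replicate 1 of 8 h and 1323 and 1213 without LA replicate 1 or 2 of 12 h, and in CLA from 13 (without any array of 8 h but CLA replicate 2) to 79. Lists ran from 0 to 5 at 4 h, 2 to 3 at 8 h, 0 to 2 at 12 h and 2 to 5 averaged. Ptpdc1 at 4 h ran from −0.063 to 4.95, because another of its probe sets became the brightest without LA replicate 1 or CLA replicate 1 of 8 h or CLA replicate 1 of 12 h.

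The replicate numbers are not known to pair samples: deviations of samples with the same number correlated at 0.0120 at 8 h and 0.0665 at 12 h, the only 2 pairs. With a replicate block shared by all times no count of genes moved by over 1.5 times, and 0 lists passed at 4 h. A replicate block within each time gave 63 genes at 4 h, 2 at 8 h, 398 for time dependence and 105 in CLA, and 0 lists at 4 h.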

Other observations

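All list tests of the change from 8 h to 12 h, the list of PPAR-activated genes and the list of nuclear-retained RNAs were chosen after the main results had been seen, while the other splits of the arrays were planned. From 8 h to 12 h in cells given CLA, 3 of the fixed lists passed camera upward. The ER chaperone list had a median log2 change of 0.18 with no member called over all genes and 10 of 20 higher adjusted over the list alone (camera adjusted p = 1.24e-04, and adjusted p = 0.0981 with an estimated correlation). The integrated stress response list had a median of 0.32 with 6 of 20 higher adjusted over the list alone (3.30e-04, and adjusted p = 0.224 with an estimated correlation), and aminoacyl-tRNA synthetases had a median of 0.14 with 1 of 14 higher adjusted over the list alone (0.00503, and adjusted p = 0.463 with an estimated correlation), again with no member of either called over all genes. Amino acid transporters did not pass (median 0.17, 1 of 10 called higher, adjusted p = 0.0960). In cells given LA these 3 lists had medians of 0.17, 0.46 and 0.20 and did not pass camera, although 9, 8 and 7 members were called higher and 4, 1 and 1 lower, and all 3 passed fry (adjusted p = 0.0155, 0.00718 and 0.0155). The median of all genes in LA was 0.13, which fry does not take into account. The difference between the LA and CLA shifts of these lists was not tested.

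Inflammatory genes shifted down in CLA over the same interval (median −0.21, adjusted p = 3.30e-04, and adjusted p = 0.0981 with an estimated correlation), with Cxcl5 and Vcam1 called lower and 4 of 20 lower adjusted over the list alone. Genes of lipid uptake and droplets had a median of −0.20, with 1 higher and 1 lower of 11 called, or 1 and 3 adjusted over the list alone (0.0491, and adjusted p = 0.313 with an estimated correlation). Adipocyte markers had a median of −0.35, with Lpl lower and 2 of 5 lower adjusted over the list alone (0.0130, and adjusted p = 0.167 with an estimated correlation). In LA the inflammatory list had 6 of 20 called lower (median −0.16) and did not pass camera (adjusted p = 0.109). It passed fry in both, at adjusted p = 0.00718 in LA and 0.00542 in CLA, and its median less that of all genes was −0.29 in LA and −0.23 in CLA. The difference between the LA and CLA shifts was not tested.

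Angptl4, Pdk4 and Cpt1a of the fatty acid oxidation list and Plin2 of the lipid droplet list, which rose in the averaged contrast, are known targets of PPAR receptors, so activation of PPAR target genes is a candidate explanation. A separate list of 20 PPAR-activated genes outside the fixed lists, 16 of them measured, had a median of −0.043 in the averaged contrast, against −0.068 for all genes (camera adjusted p = 0.849), with 2 members called higher and 1 lower. The list's median was 0.15 at 4 h (adjusted p = 0.421) and −0.35 at 12 h (adjusted p = 0.675), where 2 of the 16 members lay above 0. Members above 0 numbered 11 of 16 at 4 h, 8 at 8 h and 5 in the averaged contrast. By fry the unadjusted p was 0.0263 at 12 h, where the median of all genes was −0.15, which fry does not take into account. Most members thus lay above 0 at 4 h and below 0 at 12 h and in the average. That neither bears out nor excludes the explanation, and activation of a few targets stays open.

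For the averaged contrast, 100 of the 108 splits of the arrays within each time were fitted, with 8 not fitted. Of the 100, 3 called as many genes as the real 896, the real one included. Splits that mix the 12 h arrays put the 12 h difference between fatty acids into the spread within groups, so they could hardly call genes. The 3 of 100 therefore does not exclude a random division of the arrays. Of the 33 splits that part the arrays of 12 h by fatty acid, the real one included, 3 reached 896, so a random division of the 4 h and 8 h arrays alone is not excluded. The highest other split called 1305 genes. The 32 other splits that kept the arrays of 12 h parted by fatty acid reached 1305 with a median of 2. The 67 that mixed them called at most 2, which the larger spread within mixed groups would bring about whatever the cause.

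Several of the leading genes of 12 h, such as Tug1 (1.03) and Ncl (1.06), were lower in LA at 12 h than at 8 h, and Tug1 RNA is partly kept in the nucleus. A list of 10 nuclear-retained RNAs, 7 of them measured, had a median of 0.41 at 12 h with none called (adjusted p = 0.675, adjusted over the 8 tests of these lists).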
